A study of Mus musculus with 6 samples.

How the data were processed

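RNA was measured on Affymetrix Mouse Genome 430 2.0 arrays, 1 array per culture, in 3 wild-type and 3 Zmpste24-/- cultures of mouse embryonic fibroblasts. Per the labels, the fibroblasts came from embryos of embryonic day 13.5, were grown to passage 3, and total RNA was extracted with TRIzol. The deposited values are linear intensity per probe set, made by the authors with GCOS, Affymetrix's array software, per the submitters' processing notes. Its version, algorithm and settings are not given in the sources used here. Each array has the same mean of 500 after 2% of the probe sets is trimmed from each end, so the arrays had been scaled to one level. A change in the total RNA per cell cannot be seen after such scaling. The scanner images and the background correction were not analysed here. The number of arrays, 3 per group, limits the precision.

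The table holds 45101 probe sets, of which 64 are controls and were left out. Gene names came from the platform annotation, with symbols updated through gene identifiers in a RefSeq table of assembly GRCm38.p6. In that annotation 34945 probe sets have 1 symbol, 932 have several and 9160 are not listed. Of those with 1 symbol, 34754 were matched by gene identifier and 0 received another symbol. Probe sets with several symbols or none were tested but not named. No genome build is named in the labels, so the RefSeq table was used only for names and for which genes lie near each other.

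Values were analysed as log2(value + 16). A fold change on this scale understates the change of dim genes. The dimmest 40% of probe sets by their mean over all 6 arrays, those under a signal of 39.4, were left out, and 27022 probe sets of 13038 named genes were tested. The test was limma 3.58.1 in R 4.3.3, with an intensity trend and no block, and a Benjamini-Hochberg adjusted p under 0.05. An SE given with a log2 difference is limma's. Before the data were examined, 44 gene lists were fixed from textbook knowledge, of which 41 had at least 5 tested genes. They held 1051 genes, 895 of them tested, and each gene was represented by its brightest probe set with 1 symbol. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Those added later are named in the closing section. Figures were drawn with matplotlib 3.10.9.

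Genes were named by a rule, each by its brightest probe set with 1 symbol, and predicted genes without a symbol of their own were left out. Up to 12 rises and 12 falls were taken from genes past the threshold whose groups do not overlap in range. Where fewer passed, the remainder were taken by smallest unadjusted p under the same condition and are given as values that did not pass. Up to 4 members of each shifted list and up to 3 of any other described list were added by smallest p. Zmpste24, Lmna, Lmnb1, Icmt, Cdkn1a, Cdkn2a, Xist and Eif2s3y were always included. Trp53 and Ddx3y were on that part of the rule too, and are not analysed here because no probe set carries their symbol alone.

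The labels number the cultures 1 to 3 in each genotype and speak of 3 pairs, without saying that a number marks a pair. Deviations from the group means correlated between same-numbered cultures at 0.83, 0.59 and 0.57, over the limit of 0.1 set for calling them paired, so values with the replicate number as a block are given where they change a call. Cultures 2 and 3 also correlated across numbers, at 0.55 and 0.49, so this check tells number 1 from the other numbers better than it tells 2 from 3. On simulated data with 100 probe sets changed by 1 log2 unit and 100 by 2 log2 units, the fit without a block recovered 2% and 29% with 2 false calls. The fit with the replicate block recovered 24% and 59% with 3 false calls. The simulated values were built from the replicate effects and residual spread of the block fit. Its gain over the fit without a block was thus fixed in advance and is no evidence for the block. A simulated shift of 1 list was recovered by both fits, with 0 other lists called. It was larger than the median of any list these fits called between the genotypes at the main settings, though not of every list called in the alternatives. The simulated noise was drawn independently for each probe set. False calls of lists that arise from correlation between genes could therefore not be seen.

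Alternatives were other pseudocounts (1 and 64), no filter or a filter of 60%, quantile normalization, median centring, no intensity trend, array weights, the replicate block, a threshold of 0.1, other tests and gene representatives for the lists, and each array left out in turn.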

Results

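Gene expression was compared between wild-type and Zmpste24-/- mouse embryonic fibroblasts at passage 3, with 3 cultures of each genotype. Zmpste24 encodes the zinc metalloprotease that processes prelamin A, the precursor of the nuclear lamina protein lamin A. The comparison asks which transcripts differ in early-passage cells without it. Median signal per array lay between 56.3 and 70.5. The arrays numbered 1 stood apart from the others in both genotypes: they correlated with each other at r = 0.985 across probe sets, and with the other 4 arrays at 0.927 to 0.934, while those 4 correlated among themselves at 0.9801 to 0.987.

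Zmpste24 itself was about 10-fold lower in the cultures labelled Zmpste24-/-. Its only probe set had a signal of 2714 ± 989 in wild type and 258 ± 95.7 in Zmpste24-/- (SD, n = 3 each), or 9.50% of the wild-type mean. It was lower in each same-numbered pair, by 10.1-fold, 11.4-fold and 8.50-fold. The log2 difference was -3.31 (SE 0.34), with a limma adjusted p of 0.987 without a block and 4.0e-05 with the replicate block. The deleted part of the gene is not given in the labels, so whether the probe set lies inside it is not known here.

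Xist, the RNA that coats the inactive X chromosome, was high in wild-type culture 1 (5324) and in all 3 Zmpste24-/- cultures (6669, 4766 and 6660). It was 69.3 and 43.7 in wild-type cultures 2 and 3. The Y-linked genes Eif2s3y and Kdm5d had the opposite pattern, at 531 and 1341 for Eif2s3y and 326 and 415 for Kdm5d in wild-type cultures 2 and 3, and at most 15.7 and 12.9 in the other 4. The embryos' sex, which the labels do not give, thus differed between the genotypes in numbers 2 and 3 and not in number 1 by these transcripts. For the genes and lists below, genotype therefore cannot be told apart from sex in numbers 2 and 3. In limma with replicates 2 and 3 alone, Xist rose (adjusted p = 1.1e-06) and Eif2s3y and Kdm5d fell (7.5e-04 for both), while over all 6 arrays Xist and Eif2s3y were not called with or without the replicate block. Xist was called without wild-type replicate 1 (adjusted p = 0.00299).

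**Figure D1:**
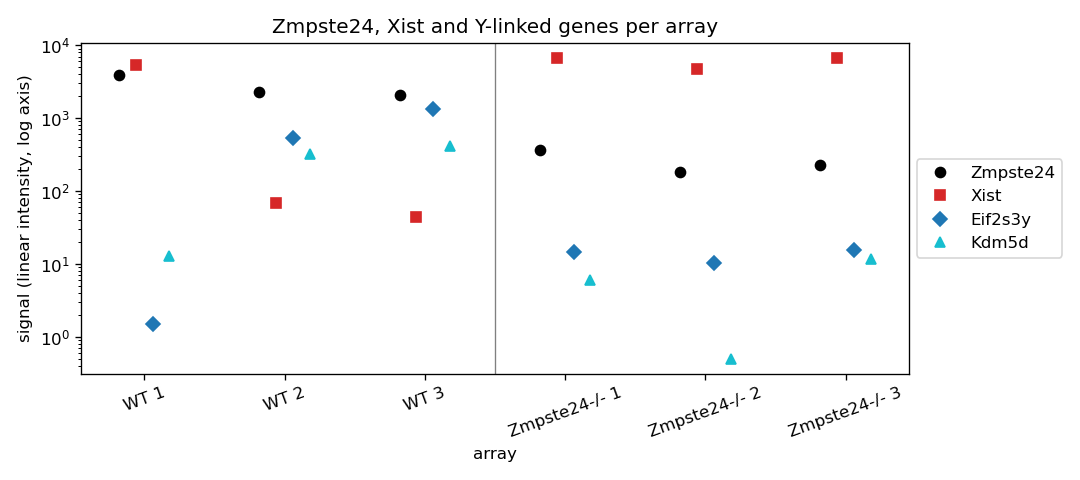
Signal of Zmpste24, Xist, Eif2s3y and Kdm5d (linear intensity on a log axis) on each of the 6 arrays, 1 point per array and gene. Zmpste24 lies at 2043 or above in wild type and at 365 or below in Zmpste24-/-, while Eif2s3y and Kdm5d are high only on wild-type arrays 2 and 3.

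Across all genes the genotypes differed little relative to the spread between cultures. In limma without a block, 0 of 27022 probe sets were called and 349 had an unadjusted p under 0.05 (120 higher, 229 lower in Zmpste24-/-), where chance alone gives 1351 for independent cultures. Number 1 stood apart in both genotypes, which widens the residual spread of this fit, so 349 cannot be read as below chance. With the replicate block 5 were called, all lower in Zmpste24-/-, and 2430 had an unadjusted p under 0.05, against the same 1351. Besides Zmpste24 these were Akirin1, which encodes a nuclear protein (log2 difference -1.72, adjusted p = 0.00898), and the ribosomal protein gene Rps6 (-0.80, 0.0334). The others were Ndufs5, a subunit of respiratory complex I (-0.73, 0.0334), and 1 probe set without a single symbol (-1.46, 0.0277). Akirin1 and the probe set without a symbol were named because the count is small, after their values were seen. A second Akirin1 probe set, the brighter of the pair, had a log2 difference of -0.14. Ptp4a2, which encodes a protein tyrosine phosphatase and was also named after its values were seen, had probe sets that disagreed, at 0.88 (groups not overlapping, unadjusted p = 0.00133), 0.09, -0.02 for the brightest, and -0.36. The groups did not overlap for 599 probe sets higher in Zmpste24-/- (2.22%) and 818 lower (3.03%). Chance gives 5% each for exchangeable cultures, which these were not, since same-numbered cultures deviated together, so the shares cannot be read as below chance.

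By the brightest probe set of each gene, the genes with the smallest p and no overlap of the groups did not pass the adjusted threshold without a block. Among those with higher values, Col10a1, the collagen of hypertrophic cartilage, had 36.1 ± 18.4 in wild type and 110.1 ± 35.1 in Zmpste24-/-, a log2 difference of 1.29 (SE 0.34). Sp7, a transcription factor of osteoblasts, differed by 0.77, Smoc1 and Ccn3, which encode secreted matrix proteins, by 0.89 and 0.82, and the guidance cue Sema3d by 0.76. The cytokine Il6 differed by 0.93 (192 ± 15.5 against 395 ± 143), the pentraxin Ptx3 by 0.79 and the activin antagonist Fst by 0.39. Gcnt1, Afap1l2, Lrrc18 and Sytl1 differed by 0.78, 0.68, 0.74 and 1.81. Among those with lower values, Retn, which encodes resistin, had 77.8 ± 12.3 in wild type and 12.9 ± 3.01 in Zmpste24-/-, a log2 difference of -1.70 (SE 0.23). The interferon-induced gene Ifi27l2a differed by -1.77, with an adjusted p of 0.0655 with the replicate block, and was called (0.0329) in a fit with number 1 as one block and numbers 2 and 3 as the other, chosen after the data were seen. Tcl1b4, Myadml2, Slc38a3 and Rab6b differed by -1.49, -1.09, -1.19 and -1.03, and Cep85, Gpr149 and Fam110c by -0.78, -0.76 and -0.61. The sizes for dim genes depend on the pseudocount: with 1 and with 64 in place of 16, Retn differed by -2.52 and -0.88, Tcl1b4 by -2.23 and -0.76, and Sytl1 by 2.56 and 1.03. The lists of collagens (12 of 22 higher, adjusted p = 0.965) and other matrix proteins (18 of 35 higher, 0.636) were not called.

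Interferon response genes were lower in Zmpste24-/- as a group. Of 29 tested members, 24 were lower, 20 of them in every same-numbered pair, with a median log2 difference of -0.47 and medians of -0.22, -0.57 and -0.61 in pairs 1, 2 and 3. The list fell with camera (adjusted p = 9.9e-07, and 7.8e-10 with the replicate block). The adjusted p = 0.979 with an estimated correlation, and 0.700 with the estimated correlation and the block, so that the call was lost. With an estimated correlation camera called no list. Even mitosis had an adjusted p of 0.385 between number 1 and the other cultures, where all 42 genes were lower by a median of 2.05. A call lost under that setting thus does not show that a list was unshifted. With fry, another test of lists, the interferon list was not called either (adjusted p = 0.9996, and 0.193 with the replicate block). At the preset correlation, splits of the arrays that mixed the genotypes also called lists, from 2 to 16 each. A small p at that setting thus does not by itself show a genotype difference. No member, by its brightest probe set with 1 symbol, passed over all genes without a block or with the replicate block. The unnamed probe set called with the block has no single symbol and so was not assigned to any list. Whether it belongs to the interferon list is not known here. With number 1 as one block, 3 members named after their values were seen fell over all genes: Rtp4 by 1.04 (adjusted p = 0.0376), Bst2 by 1.18 (0.0394) and Ifi27 by 0.62 (0.0455). Lgals3bp, an interferon-induced gene outside the list, fell by 0.76 there (0.0394), and Bst2 and Ifi27 were also called with replicates 2 and 3 alone (0.00446 and 0.0170). With the replicate block 13 members passed when adjusted over the list alone. Among these, the transcription factor Irf7 fell by 0.91 and the antiviral sensor genes Oas1a and Oasl2 fell by 1.36 and 0.78. Dhx58, a helicase of RNA sensing, differed by -0.59 and did not pass. Macrophage markers had medians of 0.84, -0.24 and -0.44 in the same pairs. With replicates 2 and 3 alone the macrophage list fell as well (adjusted p = 2.3e-05). The filter on dim probe sets used the mean over all arrays, so a marker bright only in number 1 could pass it. C1qa had 380 and 1008 in number 1, but 9.02, 8.67, 3.40 and 3.18 in the other cultures, where its fall cannot be told from background. Not every marker was so dim there: Lyz2, Csf1r and Cd68 had means of 600, 309 and 188. Without wild-type replicate 1 the interferon call was lost (adjusted p = 0.0678, median -0.29), and the median was -0.82 without Zmpste24-/- replicate 1, -0.28 without Zmpste24-/- replicate 2 and -0.30 with a pseudocount of 64.

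Glycolysis genes were lower in Zmpste24-/- by a small amount. All 16 tested members were lower, 12 in every pair, with a median of -0.16 (adjusted p = 9.9e-07, and 2.9e-09 with the replicate block). The adjusted p = 0.429 with an estimated correlation. With the replicate block 9 members passed when adjusted over the list alone, and 0 over all genes. They included the glucose transporter Slc2a1, which fell by 0.36, the lactate exporter Slc16a3, which fell by 0.75, and the enzymes Pfkl and Pkm, which fell by 0.41 and 0.18. Genes of contraction and of the transcription factor SRF were lower in 23 of 25 (median -0.10, adjusted p = 0.0207, and 0.979 with an estimated correlation). Lmod1, Cnn1, Myl9 and Cald1 in that list differed by -0.40, -0.34, -0.13 and -0.10. Ribosomal protein genes were lower in 19 of 23 (median -0.05, adjusted p = 0.0207, and 0.979 with an estimated correlation), among them Rps6 (-0.80), Rpl10a (-0.13), Rps20 (-0.09) and Rps14 (-0.09). The contractile and ribosomal calls were lost after quantile normalization (adjusted p = 0.104 and 0.576), median centring (0.108 and 0.140), with no filter (0.157 for both), with no intensity trend (0.101 and 0.209) and with the mean of a gene's probe sets (0.0741 and 0.145). They were also lost without wild-type replicate 2 (0.730 and 0.905, the ribosomal list then turning upward), without wild-type replicate 3 (0.332 for both) and without Zmpste24-/- replicate 1, where both lists turned upward (0.183 and 0.420). Array weights ended the contractile call (0.0908), and leaving out probe sets shared between transcripts ended the ribosomal call (0.106). The contractile and ribosomal medians were -0.215 and -0.14 without wild-type replicate 1 and -0.18 and -0.11 without Zmpste24-/- replicate 2, and the contractile median was -0.17 without Zmpste24-/- replicate 3.

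Cartilage and bone markers were higher in Zmpste24-/-, with medians of 0.09, 0.18 and 0.52 in pairs 1, 2 and 3, of which only pair 1 was of like sex. Of 11 tested members, 9 were higher, 4 in every pair, with a median of 0.12, a mean of 0.35 and an adjusted p of 7.9e-04 (0.00549 with the replicate block, and adjusted p = 0.429 with an estimated correlation). With the block 3 passed when adjusted over the list alone: Col10a1, Sp7 and Col2a1, the collagen of cartilage, at 1.29, 0.77 and 0.95. Sox5 differed by 0.42 and did not pass. The cartilage and bone median was 0.18 and 0.08 with pseudocounts of 1 and 64, 0.33 with array weights, 0.25, 0.28 and 0.27 without wild-type replicates 1, 2 and 3, and 0.21 without Zmpste24-/- replicate 2. With a filter of 60% fewer than 5 members were left, Col10a1 and Sp7 not among them, so the list could not be tested there. Genes of the TGF-beta pathway were higher in 14 of 24 (median 0.09, adjusted p = 0.0258, and 0.528 with an estimated correlation). Bmp4, Tgfbr1 and Id2 rose by 0.52, 0.36 and 0.30 when adjusted over the list alone with the block, and Id3 differed by 0.14. Neural and glial markers were higher in 10 of 14 (median 0.17, adjusted p = 0.0154), with medians of 0.37, 0.00 and -0.02 in pairs 1, 2 and 3. The neural call was lost with the replicate block (adjusted p = 0.0629) and with an estimated correlation (adjusted p = 0.528). Fabp7, Nefm, Stmn2 and Nefl in that list differed by 0.67, 0.81, 0.87 and 0.38. The TGF-beta call was lost without wild-type replicate 1 (adjusted p = 0.257), Zmpste24-/- replicate 2 (0.203) or Zmpste24-/- replicate 3 (0.218), with no filter (0.0557), with a filter of 60% (0.0526), with no intensity trend (0.0761) and with the mean of a gene's probe sets (0.0741). The neural call was lost without wild-type replicate 1 (0.373) or Zmpste24-/- replicate 1 (0.278), with no filter (0.439), with array weights (0.691) and in replicates 2 and 3 alone (0.773). The neural median was 0.11 with a pseudocount of 64, 0.36 with a filter of 60%, and 0.26 and 0.31 without Zmpste24-/- replicates 2 and 3.

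**Figure D2:**
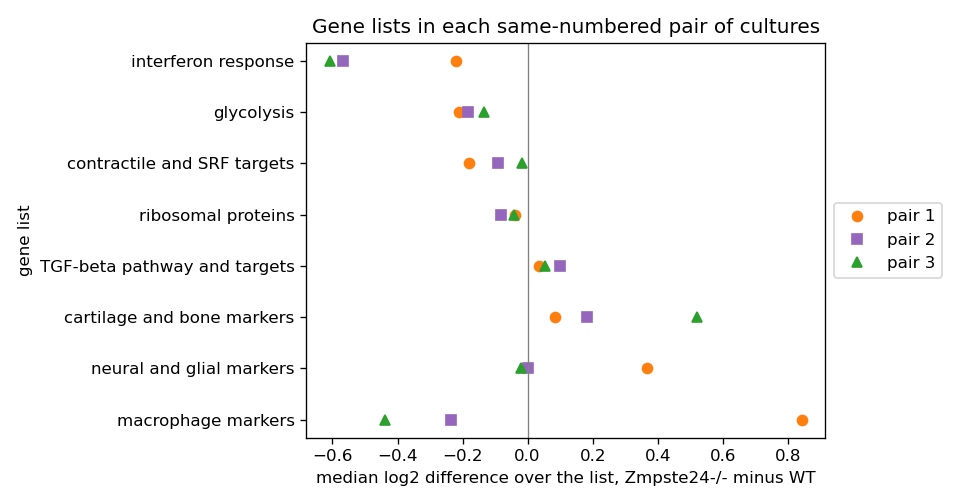
Median log2 difference (Zmpste24-/- minus wild type) over the tested genes of each shifted list and of the macrophage markers, 1 point per same-numbered pair of cultures. The interferon list lies at -0.22, -0.57 and -0.61, while the macrophage markers lie at 0.84, -0.24 and -0.44.

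With the replicate block, 10 of 41 lists were called in place of 7, and 6 were called in both. Lists called with the block and not without it were mitosis, higher in 34 of 42 (median 0.07, adjusted p = 6.6e-04 with the block and 0.397 without, with medians of -0.01, 0.22 and 0.04 in pairs 1, 2 and 3), cholesterol synthesis, lower in 17 of 19 (median -0.17, 2.0e-05 and 0.185), hypoxia targets, lower in 15 of 22 (median -0.07, 0.0107 and 0.147), and imprinted genes, higher in 11 of 18 (median 0.09, 0.0185 and 0.284). With an estimated correlation and the block their adjusted p were 0.8004, 0.745, 0.700 and 0.745. Without a block, the hypoxia list was called with a filter of 60% (0.0307), the imprinted list without Zmpste24-/- replicate 2 (0.0423), and cholesterol synthesis without wild-type replicate 1 and without Zmpste24-/- replicates 2 and 3 (medians -0.48, -0.31 and -0.32). Mitosis was called higher without wild-type replicates 2 and 3 and without Zmpste24-/- replicate 1 (medians 0.39, 0.43 and 0.79) and lower without wild-type replicate 1 (-0.59). Leaving out any 1 array gives the number 1 cultures unequal weight in the genotypes. Those cultures differed from the others by medians of -2.05 for mitosis, -0.997 for cholesterol synthesis and 0.21 for imprinted genes. The calls with an array left out thus cannot be read as genotype differences. Kif11, Spc25 and Ttk of the mitosis list differed by 0.37, 0.19 and 0.46, and Srebf2, Mvd and Nsdhl of cholesterol synthesis by -0.28, -0.25 and -0.24. Slc2a1, Bnip3 and Pdk1 of the hypoxia list differed by -0.36, -0.58 and -0.42, and Rian, Plagl1 and Igf2 of the imprinted list by 0.80, 0.32 and 0.10.

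Lists of nuclear lamina, p53 and senescence genes were not called. Lmna, which encodes lamin A and C, had 7221 in wild type and 6791 in Zmpste24-/- (log2 difference -0.11, SE 0.41). Lmnb1 differed by -0.02 (SE 0.95) and Icmt, the methyltransferase of prenylated proteins, by -0.13 (SE 0.26). The cell cycle inhibitors Cdkn1a and Cdkn2a differed by -0.12 (SE 0.17) and 0.53 (SE 1.29), with Cdkn2a higher in pair 1 only (1.98, -0.28 and -0.12). These SE values are from the fit without a block and include the gap between number 1 and the other cultures. With the replicate block they were 0.057 for Lmna, 0.082 for Lmnb1, 0.087 for Icmt, 0.055 for Cdkn1a and 0.38 for Cdkn2a. The nuclear lamina list had a median of 0.0027 over 20 genes (adjusted p = 0.668), p53 targets -0.02 over 27 (0.504), secreted senescence factors -0.04 over 32 (0.862), and DNA repair 0.07 over 36 (0.504). Among secreted factors Il6 and Ccl5 differed by 0.93 and -0.81. Sfrp2, a secreted regulator of Wnt signals, differed by 1.06 (adjusted p = 0.0750 with the replicate block) and was called with replicates 2 and 3 alone (1.21, 0.0464), in a Wnt list that was not called (0.668).

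Genes near Zmpste24 were not shifted as a group in either direction. The 97 tested genes within 5 Mb had a median log2 difference of -0.0042 (two-sided permutation p = 0.951 from 10000 random sets of genes matched on signal). Without a block 0 of them were called, as was so for all tested probe sets. With the replicate block, Akirin1 (adjusted p = 0.00898, in 1 of its probe sets) and Ndufs5 (0.0334) in this window were called, and genes with an unadjusted p under 0.05 numbered 13 in place of 3. Of these 13, 5 were higher and 8 lower in Zmpste24-/-, and a median over both directions cannot show such changes. The glucose transporter gene Slc2a1 also lies in the window.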

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

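The fits with number 1 as one block, with replicates 2 and 3 alone, and with the replicate block joined to an estimated correlation or to fry were chosen after the data were seen. Counts of probe sets higher in Zmpste24-/- were 1 with number 1 as one block, 3 with replicates 2 and 3 alone, and 0 to 1 with each array left out. Probe sets lower numbered 1 with array weights, 5 with the replicate block, 10 with number 1 as one block, 17 with replicates 2 and 3 alone (where cultures differ in sex, so that Xist is among those higher and Eif2s3y, Kdm5d, Uty and 3 unnamed probe sets of like pattern among those lower), and 0 to 3 with each array left out, the 3 without wild-type replicate 1. Shifted lists numbered 4 with no filter, with no intensity trend and with the mean of a gene's probe sets. They numbered 0 with an estimated correlation and with fry, with or without the replicate block, 11 with number 1 as one block, 13 with replicates 2 and 3 alone, and 6 to 13 with each array left out. Among lists and probe sets the replicate block changed no call beyond those given in the report. Zmpste24 was called with array weights (-3.21), the replicate block (-3.31), number 1 as one block (-3.31) and replicates 2 and 3 alone (-3.30). Lmnb1 changed sign with array weights (0.056) and with replicates 2 and 3 alone (0.031), and Cdkn2a with the latter (-0.20). With each array left out, signs changed for Lmna (-0.44 to 0.27), Lmnb1 (-0.84 to 0.86), Icmt (-0.31 to 0.065), Cdkn1a (-0.26 to 0.0096), Cdkn2a (-0.87 to 1.57), the genes near Zmpste24 (-0.025 to 0.024), mitosis (-0.59 to 0.79), cholesterol synthesis (-0.48 to 0.20), contractile genes (-0.215 to 0.082) and ribosomal proteins (-0.14 to 0.028). Leaving out any 1 array unbalances the groups. The arrays of number 1 stand apart and then weigh differently in the genotypes, which by itself moves the difference of genes that set number 1 apart. How much of each change this accounts for was not tested. The cartilage and bone list and Col10a1, Gcnt1, Sp7, Sytl1, Lrrc18, Retn, Tcl1b4, Myadml2, Slc38a3 and Rab6b, too dim for the 60% filter, gave no value there. The log2 differences of Col10a1, Sp7, Sytl1, Retn, Tcl1b4, Myadml2, Slc38a3 and Rab6b shrank by over 1.5 times with a pseudocount of 64, to 0.79, 0.51, 1.03, -0.88, -0.76, -0.62, -0.67 and -0.66. Smoc1 shrank likewise with array weights (0.57) and with replicates 2 and 3 alone (0.46), and Ptx3 without wild-type replicate 2 (0.51). Among called lists the medians that moved by over 1.5 times with another pseudocount, filter or array weights were those of the interferon, neural, and cartilage and bone lists given in the report and the neural median with no filter (0.08) and with array weights (0.07), and that of the TGF-beta list moved with the mean of a gene's probe sets (0.03) and that of the ribosomal list with quantile normalization (-0.0080).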

Other observations

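The cultures numbered 1 differed from the others far more than the genotypes did. With genotype in the model, 12671 of 27022 probe sets (46.9%) were called between number 1 and numbers 2 and 3, of which 6773 were higher and 5898 lower in number 1. All 42 mitosis genes were lower there, with a median log2 difference of -2.05, and 35 of 40 DNA replication genes (median -1.36). The proliferation marker Mki67 had a mean of 490 in number 1 and 2616 in the others, and Lmnb1 400 and 2424. Cdkn2a was higher in number 1 (1389 against 128), as were the growth factor Igf1 (2861 against 234) and 16 of 17 macrophage markers (median 2.24), such as Lyz2 (5705 against 600). Cholesterol synthesis genes were lower in 18 of 19 (median -0.997). None of these lists was called with an estimated correlation, where the smallest adjusted p was 0.385. These genes were picked after their values were seen, and number 1 holds 1 culture of each genotype.

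In the paragraphs that follow, the tests of embryo sex, macrophages and sequence near Zmpste24 were chosen after the results were seen, while the other splits of the arrays were planned. The 6 arrays make 10 splits, too few for a share under 0.05. For probe sets higher the real split gave 0 and the highest other 0, so that 10 of 10 gave as many, and for probe sets lower 0 and 3, again 10 of 10. For lists, 5 of 10 splits gave at least the real 7, and the highest other gave 16. The 4 splits with both number 1 arrays on one side gave 11 to 16 lists, which points to the structure of the samples. Among the 4 splits that part all 3 pairs, the real one gave 7 lists and the others 2 or 3, and with the replicate block the real one gave 5 probe sets and the highest other 1 (1 of 4 as large).

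The interferon list was lower in Zmpste24-/- in each pair, and in pair 1, where both cultures had high Xist, its median was -0.22. Gaps between cultures of one genotype were 0.01 and -0.11 between cultures 2 and 3, but with genotype in the model the list was higher in number 1 than in numbers 2 and 3 by a median of 0.798 (19 of 29 members called). With 1 pair of like sex and cultures of one genotype that differ by this much, a difference in embryo sex cannot be told apart from genotype. A smaller share of macrophages is argued against in pair 1, where the macrophage markers were higher in Zmpste24-/- (median 0.84, lower quartile 0.54, 17 genes, among them the abundant Lyz2 at 0.77). In pairs 2 and 3 fewer macrophages may still contribute, and the values cannot decide it. There the interferon median lay below the macrophage median by a log2 difference of -0.26, with a 95% bootstrap interval over genes of -0.46 to 0.17. Markers such as C1qa (9.02 and 8.67 in wild type, 3.40 and 3.18 in Zmpste24-/-) were near background in these cultures, and the pseudocount shrinks their differences. The macrophage median there thus does not measure a share of macrophages. The brighter Lyz2, Csf1r and Cd68 fell in pairs 2 and 3, with log2 differences of -0.35 and -0.86, -0.24 and -0.16, and -0.15 and -0.44. Adgre1, C1qb, Cd52 and Cd53 were higher in Zmpste24-/- in pair 2. The interval also leaves out correlation between genes and the spread between cultures.

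All 3 named genes called with the replicate block besides Zmpste24 (Akirin1, Rps6 and Ndufs5) lie on its chromosome, which holds 5.98% of the tested genes, and Ptp4a2, called higher in 1 probe set with number 1 as one block, lies there too, although that fit also called genes elsewhere such as Bst2, and a candidate explanation is flanking sequence of the strain in which the gene was targeted. In the planned window, which does not hold Rps6, 13.4% of its 97 genes had p under 0.05 with the replicate block, against a median of 9.28% in 10000 random sets (two-sided permutation p = 0.228). The share was 13.9% of 173 genes at 10 to 20 Mb, and 11.8% of the 780 genes on the chromosome against 8.92% elsewhere, neither of them tested. Of 10 distance bins viewed before this test, the highest share was 21.9%, in 32 genes, a bin picked by its value and so no test. Sequence differences under single probe sets could also act, but the median SD of the log2 difference among probe sets of a gene was 0.105 in the window and 0.107 in random sets (two-sided permutation p = 0.959), and both explanations stay open.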
